A study of Mus musculus with 12 samples.

How the data were processed

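Gene expression was measured by RNA-seq, and CpG methylation by enhanced reduced representation bisulfite sequencing (ERRBS), in pellets of mouse articular chondrocytes harvested at Week 1 (day 7) or Week 3 (day 21). Each assay had 3 libraries per week, 12 libraries in all. Per the labels, the cells came from the femoral heads and tibial plateaus of C57BL/6J pups and were expanded in monolayer before pelleting. The labels do not say whether replicates were separate cultures or separate animals, so p-values measure the spread between these samples only.

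For RNA-seq, the deposited values were raw read counts per RefSeq transcript. Per the submitters' processing notes, base calls came from CASAVA 2.17 and reads were counted with featureCounts after alignment to mm10 with STAR. The series description adds adapter trimming with Flexbar and default STAR parameters. Versions of STAR and featureCounts, and the strand setting of the counting, are not given in the sources used here. The library protocol describes poly A selection and random hexamer priming and no strand marking, so reads of genes that overlap on opposite strands cannot be told apart. For ERRBS, the authors deposited 1 file per library that lists each cytosine of a CpG with its coverage, a count of reads, and, per the file headers, the percent of those reads that showed C (methylated) or T (unmethylated). The sites were listed from 10 reads upward, strands separate. The submitters' processing notes name Bismark for bisulfite data, and the series description names methylKit and eDMR. The Bismark version and any removal of duplicate reads are not given in the sources used here.

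Each RNA-seq table held 30048 transcript accessions. RefSeq and GENCODE annotation tables of mm10 paired all but 394 with a gene symbol. These 394 carried 1.53% of all counts and were kept, each as a gene of its own. Transcripts of a gene shared reads: in 2581 genes with at least 2 well counted transcripts, the lowest count was in the median 0.984 times the highest. The value of a gene was therefore the count of its transcript with the highest total, a choice made after the tables had been seen, which left 23575 genes. Gene totals per library ranged from 14361717 to 19774665 counts. Reads are not independent molecules, so floors and intervals given with a value cover counting error only.

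Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr, and the robust quasi-likelihood F test of Week 3 against Week 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene is from this test unless another tool is named. The 26 gene lists fixed before the data were examined were hypertrophic chondrocyte, permanent and proliferating cartilage, superficial zone and synovial lining, fibroblast and dedifferentiated chondrocyte, osteoblast and mineralisation, extracellular matrix proteases and inhibitors, cell cycle and DNA replication, DNA methylation machinery, Wnt signalling, BMP and TGF-beta signalling, hedgehog signalling, hypoxia and glycolysis, oxidative phosphorylation, interferon response, inflammation and NF-kB, ER stress and unfolded protein response, cholesterol synthesis, posterior and limb Hox genes, adipocyte, macrophage and leukocyte, osteoclast, endothelial, smooth muscle and pericyte, skeletal muscle, erythroid, and neural and Schwann cell. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists tested. Camera at an estimated correlation and fry were the alternatives. Camera compares a list's members with the other genes. The fry test asks only whether the members changed, so its pass does not set a list apart from other genes. In splits of the RNA-seq libraries that mix both weeks, camera at the preset called 4 to 11 lists while 0 genes passed. Counts of members that passed are also given adjusted over the list alone. Member counts stand against 5361 of 14323 genes called in all, 2815 higher and 2546 lower.

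The genes named were set by a rule written before the data were examined. The rule took a fixed panel of cartilage, hypertrophy and methylation genes, and up to 4 members of each list with the smallest adjusted p. It added the 10 largest rises and 10 largest falls among genes that passed, averaged at least 5 CPM and had no overlap between weeks. CPM values are counts scaled to the library total after its TMM normalisation. For methylation, the rule took the 3 smallest p where no tile or promoter passed, and the promoters of the panel genes. Some genes that the rule selects are not reported here. Other named genes and tiles were chosen after their values had been seen. A gene's CPM is given as the mean ± SD of 3 libraries. Its log2 change is given with an approximate standard error (SE), the absolute log2 change over the square root of the test's F value.

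Methylation was compared at CpG sites of chromosomes 1 to 19 and X covered at least 10 times in all 6 libraries. Methylated and unmethylated reads were tested per site, per 1000-base tile with at least 3 sites, and per promoter, from 1500 bases upstream to 500 bases downstream of the 5′ end of the gene with at least 3 sites. The test was a quasi-binomial logistic model with an overdispersion term per feature, moderated across features with limma, an F test and Benjamini-Hochberg adjustment. Mean levels per library were compared with 2-sided exact permutation tests, whose smallest possible p with 3 libraries against 3 is 0.1. Promoter and expression changes were correlated across genes with 100000 permutations, and overlaps were tested with Fisher's exact test.

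Both tests were tested on simulated data. In RNA-seq counts, the edgeR test called 66% of genes changed 1.5-fold, 82% at 2-fold and 94% at 4-fold, with 20 false calls among 189. In tiles, changes were placed only in tiles of intermediate methylation level, so power at low or high levels was not simulated. There the 6-library test recovered 0 of 100 tiles changed by 20 points and 13 of 100 changed by 30 points with 0 false calls. Without Week 3 replicate 2 it recovered 3 and 34, again with 0 false calls, and a logistic test without the overdispersion term made 24145 false calls. The simulation gave all tiles of a library the same overdispersion, so its false calls do not cover tiles that vary more. In other splits of the real 5 libraries without Week 3 replicate 2, the quasi-binomial test called up to 9 tiles and 13 promoters.

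Week 1 and Week 3 samples carry the same replicate numbers. In RNA-seq, same-numbered libraries deviated together from their group means, with correlations of 0.259, 0.376 and 0.194 for replicates 1, 2 and 3 against at most 0.061, -0.189 and 0.061 with another number. The numbers may therefore pair these libraries. Deviations from a mean of 3 libraries are not independent of each other, so this check cannot establish the pairing. The labels do not state a pairing. The main test has no block, and the blocked value stands beside a result whose call it changed.

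The alternatives fixed beforehand were DESeq2 1.42.0, other size factors, other count filters, a 1.5-fold threshold (glmTreat), the replicate block, each library left out in turn, and for methylation other coverage limits, merged strands, autosomes alone, other tile and promoter sizes, edgeR, and tests without overdispersion or without moderation. Alternatives added after the data had been seen were summing a gene's transcripts, leaving out replicate 2 of both weeks in RNA-seq, joining the ERRBS sites over 5 or 4 libraries, a limma weight per library, and promoters placed at the counted transcript. Sites on chromosome Y, on unplaced sequences and on mitochondrial DNA were left out of the tests. Tables were handled with pandas 2.3.3, data.table (version 1.17.8), numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 in Python 3.11.15.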

Results

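Articular chondrocytes from mouse pups were kept as pellets, small 3-dimensional aggregates that drive the cells towards hypertrophy, for 1 or 3 weeks. RNA and DNA came from separate libraries, 3 per week and assay. The RNA-seq libraries held 15893390, 15853559 and 14361717 gene counts at Week 1 and 15988688, 19774665 and 17354588 at Week 3, for replicates 1, 2 and 3. The ERRBS libraries listed 2087029, 2131385 and 1220867 cytosines at Week 1 and 1861218, 1653714 and 1770003 at Week 3. Their median coverage was 41, 47 and 16 reads at Week 1 and 26, 15 and 22 reads at Week 3. At the 724670 cytosines covered at least 10 times in all 6 libraries, median coverage ran from 17 reads (Week 1 replicate 3) to 66 reads (Week 1 replicate 2).

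The comparison of RNA at Week 3 with Week 1 asked how expression changed as the pellets moved towards hypertrophy. Col10a1, the collagen of hypertrophic cartilage, rose 16.1-fold, from 250.6 ± 22.5 to 4035 ± 1383 CPM (SD, n = 3). Ihh, the hedgehog ligand of prehypertrophic chondrocytes, rose 25.2-fold, from 0.860 ± 0.354 to 21.4 ± 4.30 CPM. Alpl, the alkaline phosphatase of mineralising cells, rose 19.5-fold, to 1171 ± 173 CPM, and Ibsp, a bone matrix protein, rose 43.4-fold, from 268 ± 20.1 to 11620 ± 1260 CPM. Of 14323 genes tested with edgeR, 5361 changed, 2815 higher and 2546 lower at Week 3. At least 2-fold differences were found for 695 higher and 293 lower genes, and at least 4-fold differences for 161 higher and 45 lower genes. Against a 1.5-fold threshold (glmTreat), 742 genes passed.

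Of 22 tested members of the hypertrophic chondrocyte list, 20 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 5.24e-57, and adjusted p = 0.0562 with an estimated correlation). Col10a1 (chromosome 10, bases 34389981 to 34397085 in mm10) had a log2 change of 4.01 ± 0.27 (SE, adjusted p = 0.000105), and Mmp13 (chromosome 9, bases 7272514 to 7283333), a collagenase, rose from 230 ± 11.3 to 923 ± 178 CPM (adjusted p = 2.95e-05). Runx2, a transcription factor of hypertrophy and bone, rose 3.32-fold (adjusted p = 5.63e-05), Mef2c rose 4.91-fold and Spp1, osteopontin, rose 1.80-fold (adjusted p = 0.00529). Vegfa and Foxa2 were the members that did not pass, with log2 changes of 0.16 and 0.28.

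In the osteoblast and mineralisation list, 11 of 13 tested members rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 5.07e-21). This was the single list that passed with an estimated correlation (adjusted p = 0.0128). Phex, a peptidase of bone cells, rose 53.1-fold, from 1.79 ± 0.325 to 94.4 ± 15.0 CPM, and Dmp1, a matrix protein of late bone cells, rose from 5.13 ± 1.44 to 61.3 ± 7.80 CPM. Bglap, osteocalcin, had 2 counts at Week 1 and 219 at Week 3 (ratio 95.1, 95% exact binomial interval 26.0 to 790), and its near-identical neighbour Bglap2 makes the split of reads between them uncertain. The members that fell were Enpp1 and Ank, which supply extracellular pyrophosphate, an inhibitor of mineral growth, with log2 changes of -0.53 and -0.52.

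Cartilage matrix genes moved in different directions. In the permanent and proliferating cartilage list, 12 of 26 members rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.0061, and adjusted p = 0.637 with an estimated correlation; fry adjusted p = 0.0596). Acan, the large proteoglycan of cartilage, rose 2.98-fold, from 2111 ± 618 to 6287 ± 160 CPM (adjusted p = 0.00158). Hapln1, which links aggrecan to hyaluronan, rose 2.22-fold, Chad 4.12-fold and Sox6 1.77-fold, while Ucma and Epyc fell by 1.48 and 1.45 on the log2 scale. Col2a1, the main collagen of cartilage, was at 11880 ± 4714 CPM at Week 1 and 12630 ± 913 CPM at Week 3 (log2 change 0.09 ± 0.30, adjusted p = 0.843). The Week 1 spread came from replicate 2, at 6534 CPM against 15430 and 13670, and without it the log2 change was -0.21 (adjusted p = 0.0732). Without that library 14 members of the list rose and 6 fell, Col9a1, Matn1, Cnmd and Col9a3 now among them (adjusted p = 0.00158, 0.00178, 0.00327 and 0.0154), and Col9a1 also passed with the replicate block (adjusted p = 0.0117). Sox9, the transcription factor of the chondrocyte lineage, had a log2 change of 0.21 ± 0.17 (adjusted p = 0.358).

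In the fibroblast and dedifferentiated chondrocyte list, 9 of 15 members rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.55e-09, and adjusted p = 0.147 with an estimated correlation). Without Week 1 replicate 1, 6 rose and 0 fell, and no member fell without Week 1 replicate 2 or Week 3 replicate 1 or 3 either. Col1a1 rose 4.41-fold, from 1552 ± 514 to 6838 ± 268 CPM, Col1a2 rose 4.55-fold to 22490 ± 1953 CPM, and Tnc and Fap rose 3.56-fold and 3.52-fold. In the superficial zone and synovial lining list, 4 of 12 rose and 1 fell, the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.116; fry adjusted p = 0.00114). The count of falls was 3 without Week 1 replicate 2 and 0 without Week 3 replicate 2 or 3. Erg rose 2.44-fold and Cilp 1.80-fold, and Prg4, the lubricant of the joint surface, had a log2 change of 0.07 ± 0.09 (adjusted p = 0.557). In the extracellular matrix proteases and inhibitors list, 11 of 20 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.473 with an estimated correlation). Those 4 falls came to 0 without Week 3 replicate 1 or 2, and to 2 without Week 1 replicate 1 or 3 or Week 3 replicate 3. Adamts9 rose 3.54-fold, Htra1 1.64-fold and Ctsk 1.74-fold.

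In the hedgehog signalling list, 5 of 10 members rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 4.9e-05, and adjusted p = 0.154 with an estimated correlation). Hhip, Ptch1 and Gli1, all targets of the pathway, rose 21.3-fold, 5.20-fold and 4.63-fold, and Ptch1 reached 404 ± 36.1 CPM from 77.8 ± 13.4. The transcription factor Foxf1 fell by 1.12 on the log2 scale. In the Wnt signalling list, 15 of 24 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 9.71e-09, and adjusted p = 0.154 with an estimated correlation). The secreted inhibitors Wif1 and Frzb rose 6.93-fold and 2.60-fold, and the ligands Wnt5a and Wnt5b 2.63-fold and 4.62-fold. The member that fell, Sfrp1, is also a secreted inhibitor (log2 change -1.16, adjusted p = 0.031). It lost its call without Week 1 replicate 1, 2 or 3 (adjusted p = 0.0507, 0.0912 and 0.07) and without Week 3 replicate 1 or 3 (0.0706 and 0.0858), and without Week 3 replicate 2 the list had 2 falls. Dkk1, another inhibitor, had 0 counts at Week 1 and 107 at Week 3, at least 31.0-fold higher against a floor of 3 counts over the group, with a lower 95% exact binomial limit of 24.7, and the list's median log2 change of 1.11 was the same with Dkk1 at that bound. In the BMP and TGF-beta signalling list, 12 of 26 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.0106, and adjusted p = 0.257 with an estimated correlation). The ligands Tgfb3 and Tgfb2 rose 2.19-fold and 1.44-fold, and Id2 and Smad7 fell by 0.49 each on the log2 scale.

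In the cell cycle and DNA replication list, 13 of 26 members rose and 5 fell (16 and 5 adjusted over the list alone; camera adjusted p = 0.0109, and adjusted p = 0.473 with an estimated correlation). The 5 falls came to 2 without Week 1 replicate 3 or Week 3 replicate 1, and to 3 without Week 1 replicate 1 or Week 3 replicate 2 or 3. Mki67, the proliferation marker, rose 3.17-fold, from 23.4 ± 4.81 to 74.1 ± 16.2 CPM, Top2a rose 1.96-fold and Kif11 2.77-fold. The replication genes Pcna and Mcm3 fell by 0.41 and 0.38 on the log2 scale, and Mcm6 rose 1.70-fold. In the DNA methylation machinery list, 6 of 21 rose and 3 fell (7 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.61). The counts were 8 and 1 without Week 3 replicate 1. Tet1, an enzyme that oxidises methylcytosine, rose 1.81-fold, Tet3 rose 1.35-fold, and Uhrf1, which recruits the maintenance methyltransferase, rose 2.17-fold from 2.93 ± 0.722 CPM. Dnmt3a, a de novo methyltransferase, rose 1.30-fold (adjusted p = 0.0123), a call lost without Week 3 replicate 2 (adjusted p = 0.0504). Tet2 fell by 0.19 on the log2 scale (adjusted p = 0.0128), a call lost without Week 3 replicate 1 (adjusted p = 0.0603). Dnmt1, the maintenance methyltransferase, had a log2 change of 0.20 ± 0.08 (adjusted p = 0.0805), which passed with the replicate block (adjusted p = 0.0401) and without Week 3 replicate 1 (adjusted p = 0.0466). Dnmt3b had one of -0.20 ± 0.17 (adjusted p = 0.389).

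**Figure D1:**
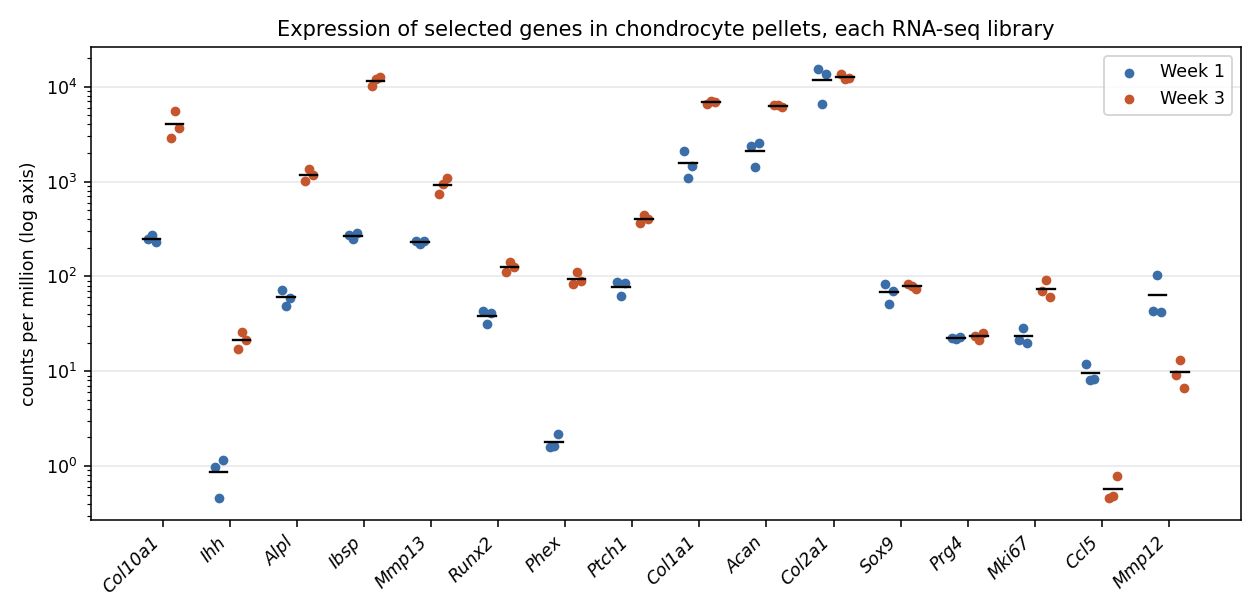
CPM (log axis) of 16 genes in the 3 Week 1 and 3 Week 3 RNA-seq libraries, each point a library and each bar the mean of its week. Col10a1, Ihh, Alpl, Ibsp, Phex and Ptch1 separate fully between the weeks, and Col2a1 shows the low value of Week 1 replicate 2 at 6534 CPM.

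Among the 10 largest rises, Ptprz1, a receptor phosphatase, had 1 count over the Week 1 libraries and 4871 at Week 3 (ratio 4230, 95% exact binomial interval 759 to 167000). Adamts18, Slc13a5, Entpd3, Col13a1 and Insc rose by log2 changes of 7.63, 7.58, 5.99, 5.89 and 5.35. Panx3, a channel of hypertrophic chondrocytes and osteoblasts, rose 43.9-fold, from 4.74 ± 1.95 to 206 ± 23.1 CPM. Slc13a5, Acan, Adamts9, Gli1, Phospho1, Prg4, Epyc, Tagln, Ncam1, Plin4, Alas2, Atf5 and Ddit3 have exons that overlap another gene's, so part of their counts is uncertain. Among the 10 largest falls, the chemokine Ccl5 fell by 4.02 on the log2 scale, from 9.47 ± 2.22 to 0.578 ± 0.187 CPM (adjusted p = 4.61e-06). Nptx1, Atp6v0d2, Gipr and Acer2 fell by 2.83, 2.57, 2.22 and 2.17. The others, Clec4d, Mmp12, Ctss, Lilrb4a and Nckap1l, fell by 3.17, 2.70, 2.15, 2.03 and 1.93. Mmp12 lost its call without Week 3 replicate 1, 2 or 3 (adjusted p = 0.0597, 0.0506 and 0.0538), and Lilrb4a without Week 1 replicate 2 (adjusted p = 0.0581). Without Week 1 replicate 1, Week 1 replicate 2 or Week 3 replicate 2, Ctss lost its call (adjusted p = 0.0786, 0.0812 and 0.0827), as did Nckap1l (adjusted p = 0.102, 0.124 and 0.135).

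Markers of other cell types moved apart. In the macrophage and leukocyte list, 6 of 13 fell and 0 rose, the same adjusted over the list alone, and camera did not pass (adjusted p = 0.0715, and adjusted p = 0.684 with an estimated correlation; fry adjusted p = 0.2). It passed with the replicate block (adjusted p = 0.00466), without Week 1 replicate 3 (adjusted p = 0.0196) and without Week 3 replicate 1 (adjusted p = 0.00419). The count of falls was 1 of 13 without Week 1 replicate 1, where Cd14 alone passed, and was 3 without Week 3 replicate 2. It was 5, with 1 rise, without Week 3 replicate 3. Cd14 fell by 0.71 on the log2 scale, from 8.10 ± 1.33 to 4.98 ± 0.870 CPM. In the osteoclast list, Atp6v0d2 and Itgb3 fell (2 of 4, the same adjusted over the list alone; camera adjusted p = 0.0287, and adjusted p = 0.215 with an estimated correlation), and the call was lost without Week 1 replicate 1 (adjusted p = 0.0552). In the smooth muscle and pericyte list, 4 of 9 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0254, and adjusted p = 0.213 with an estimated correlation). Acta2 rose 4.76-fold, to 90.6 ± 22.9 CPM, and Tagln 3.47-fold, but the list's call was lost with the replicate block (adjusted p = 0.109) and without Week 1 replicate 1 (adjusted p = 0.0565). In the neural and Schwann cell list, 6 of 7 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.154 with an estimated correlation). Without Week 1 replicate 3 or Week 3 replicate 1, 3 rose. Ncam1 rose 1.79-fold from 105 ± 4.78 CPM and Mbp 1.87-fold from 28.0 ± 5.31 CPM.

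The adipocyte list had 1 of 12 members called, Retn, and 0 adjusted over the list alone, and camera did not pass (adjusted p = 0.389). Retn, at 1.07 ± 0.227 CPM at Week 1 and 0.359 ± 0.260 at Week 3, lost its call without Week 1 replicate 1 (adjusted p = 0.0972), Week 1 replicate 3 (0.0577), Week 3 replicate 1 (0.0781) or Week 3 replicate 3 (0.0803). Without Week 3 replicate 2, 2 members fell. Replicate 2 of each week had the highest mean over the list, at a log2 CPM of 4.03 at Week 1 and 3.62 at Week 3 against 1.56 to 2.78 in the other libraries. With the replicate block 7 of the 12 members fell and 1 rose, and the list passed lower (adjusted p = 0.0165). Those that fell included the fatty acid receptor Cd36 (log2 change -1.41, adjusted p = 9.85e-06) and Cebpa (-0.65, adjusted p = 0.00465). Without Week 3 replicate 2 and with no block, Cebpa had an adjusted p of 0.033. The lipid droplet gene Plin4 passed higher with the block (0.61, adjusted p = 0.000102). Using replicates 1 and 3 of each week alone, 6047 genes and 12 lists were called. In the endothelial list, 1 of 4 rose and 2 fell, the same adjusted over the list alone, and camera did not pass (adjusted p = 0.559). With fry the list passed higher (adjusted p = 0.00745), but its 1 rise was Erg, also a member of the superficial zone list. Flt1, Egfl7 and Vwf had log2 changes of -0.71, -0.58 and -0.25. The falls came to 0 without Week 1 replicate 1 or Week 3 replicate 3 and to 1 without Week 1 replicate 2 or Week 3 replicate 1 or 2. In the skeletal muscle list, 1 of 3 fell, the same adjusted over the list alone (camera adjusted p = 0.11; fry adjusted p = 0.00319). That member was Ttn, lower by a log2 change of -1.57, while Tnnt3 and Mylpf had log2 changes of 0.20 and 0.23 and were not called. The list passed camera lower without Week 1 replicate 1 (adjusted p = 0.000436) or without Week 3 replicate 1, 2 or 3 (0.0322, 0.0484 and 0.023). The erythroid list had 1 tested member, Alas2 (log2 change -0.08, adjusted p = 0.522), and was not tested.

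**Figure D2:**
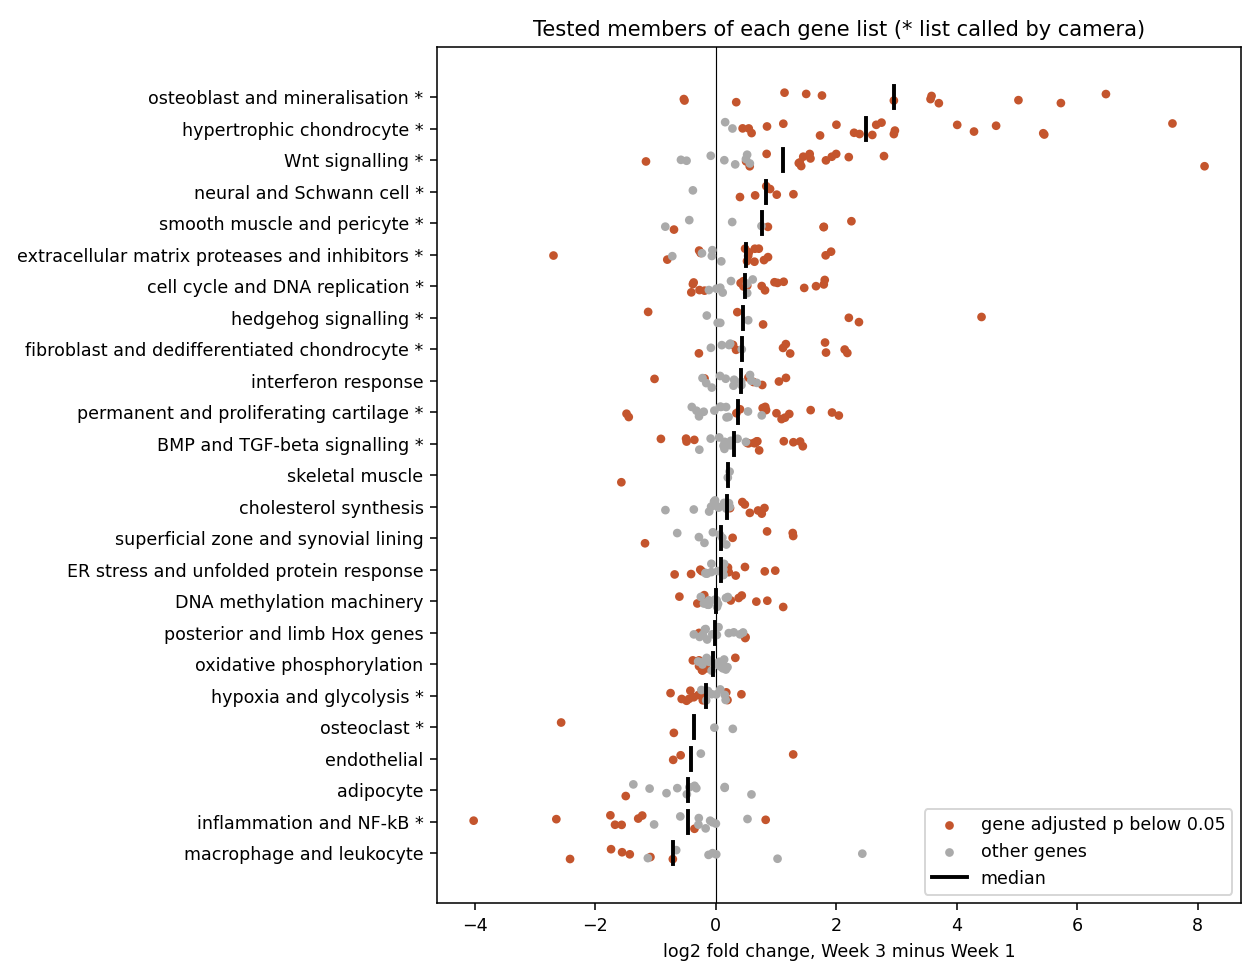
Log2 fold change (Week 3 minus Week 1) of the tested members of each of the 25 lists, with a bar at the list's median and an asterisk where camera passed. The osteoblast and hypertrophic lists lie highest, with medians of 2.96 and 2.49.

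The comparison of DNA methylation at Week 3 with Week 1 asked where methylation changed over the same interval. Sites away from CpG-dense sequence had slightly lower methylation in all 3 Week 3 libraries than in any Week 1 library. At sites in sequence with 10 or fewer CpGs per kb the mean went from 74.57% ± 0.18 to 73.45% ± 0.09 (SD, n = 3; difference -1.12 points), between genes from 60.95% ± 0.18 to 60.20% ± 0.13 (-0.75 points) and in introns from 53.54% ± 0.13 to 52.93% ± 0.09 (-0.61 points). Each had an exact permutation p of 0.1, the smallest that 3 against 3 can give, so these differences cannot pass 0.05. In promoter windows the mean was 3.88% ± 0.03 and 3.94% ± 0.24 (exact p = 0.9), and in exons the difference was -0.04 points (exact p = 0.8). Without Week 3 replicate 2 the difference was -0.07 points in promoter windows and -0.22 points in exons. Over all shared sites the difference was -0.305 points (exact p = 0.1). When reads were pooled instead of averaging sites it was 5.775 points, the opposite direction with the same exact p of 0.1. Pooling weights each site by its depth in that library, so the pooled value also reflects which sites took up the reads. By site averages no site class rose by more than 0.1 points.

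**Figure D3:**
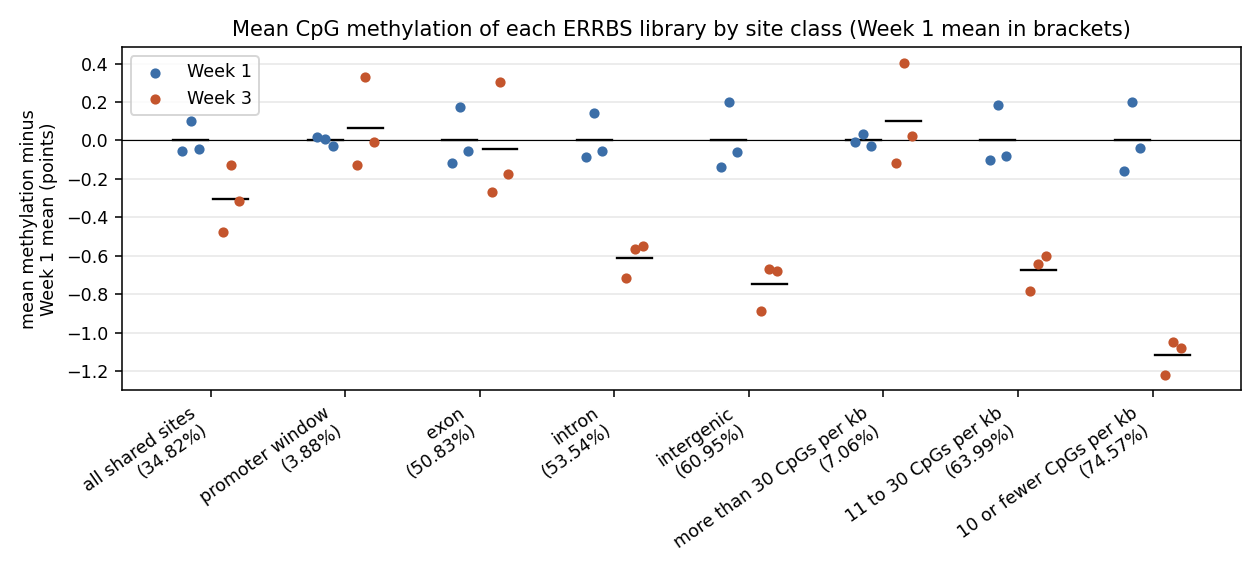
Mean methylation of each ERRBS library minus the Week 1 mean of its site class, in percentage points, with a bar at the mean of each week and the Week 1 level in brackets. Sites with 10 or fewer CpGs per kb lie lowest at Week 3, by -1.12 points, and promoter windows lie near 0.

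No single region passed the test that allows for spread between replicates. The quasi-binomial test called 0 of 568192 sites, 0 of 71017 tiles and 0 of 13570 promoters, with 38717, 4603 and 988 at an unadjusted p under 0.05. edgeR called 7 sites and 0 tiles, and a logistic test without overdispersion called 43447 sites, 15808 tiles and 4564 promoters. The 3 tiles with the smallest p lay in introns and were lower at Week 3 in every library, each with an adjusted p of 0.182. In Steap3, a metalloreductase (chromosome 1, bases 120236001 to 120237000), the level was 38.0% ± 5.2 and then 12.4% ± 3.0, over 232 to 752 reads per library. In Dap (chromosome 15, bases 31237001 to 31238000) it was 86.7% ± 4.8 and then 55.2% ± 11, and in Sdk2 (chromosome 11, bases 113951001 to 113952000) 48.6% ± 3.4 and then 20% ± 6.1.

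Calls depended on which library was left out. Without Week 3 replicate 2, the quasi-binomial test called 24 of 70942 tiles, 22 lower and 2 higher at Week 3, with 11 of the 22 in introns, 4 in exons, 7 between genes and 0 in promoter windows. In an intron of Cda, a cytidine deaminase (chromosome 4, bases 138356001 to 138357000), the level was 83.8% ± 5.2 and then 32.7% ± 22.2. In an exon of Git2 it was 73.2% ± 2.6 and then 34.4% ± 9.5, and an intron of Ago2 changed by -29.6 points. The higher tiles were an exon of Angptl6 (8.9 points) and the promoter window of Fbxl4 (5 points). Each gain came mostly from 1 library, with Week 3 replicates 1 and 3 at 2.5% and 15.6% in Angptl6 and at 8.3% and 1.7% in Fbxl4. The library left out stood at 0% in both tiles, over 450 and 273 reads. Without Week 3 replicate 3, 2 tiles were called, in Dap and in an exon of Snd1, each with an adjusted p of 0.0296 and each also among the 24. With any other library left out 0 tiles were called. In the 5 libraries other than Week 3 replicate 2, joined alone, 35 of 97461 tiles were called, 33 lower and 2 higher, with a median fall of -24.4 points among the 33, and 22 were shared with the 24. In single sites, 2, 6 and 2 were called without Week 3 replicates 1, 2 and 3, and all were lower at Week 3. The 2 called each time lay at bases 98662795 and 98666504 of chromosome 2, between genes, and changed by -3.8 and -3.1 points without replicate 2. Their quasi-binomial adjusted p values there were 5e-04 and 1.39e-06, and whether reads mapped uniquely at these 2 sites was not checked. Over all libraries the smallest quasi-binomial adjusted p of any site was 0.251, and 0.674 without the sites of highest coverage. The fits with 1 library left out were not repeated without the sites of highest coverage. The other sites called lay in Git2, Igf1r and Crispld2 and near Epas1. The Git2 site changed by -53.3 points with a larger quasi-binomial adjusted p of 0.0356.

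**Figure D4:**
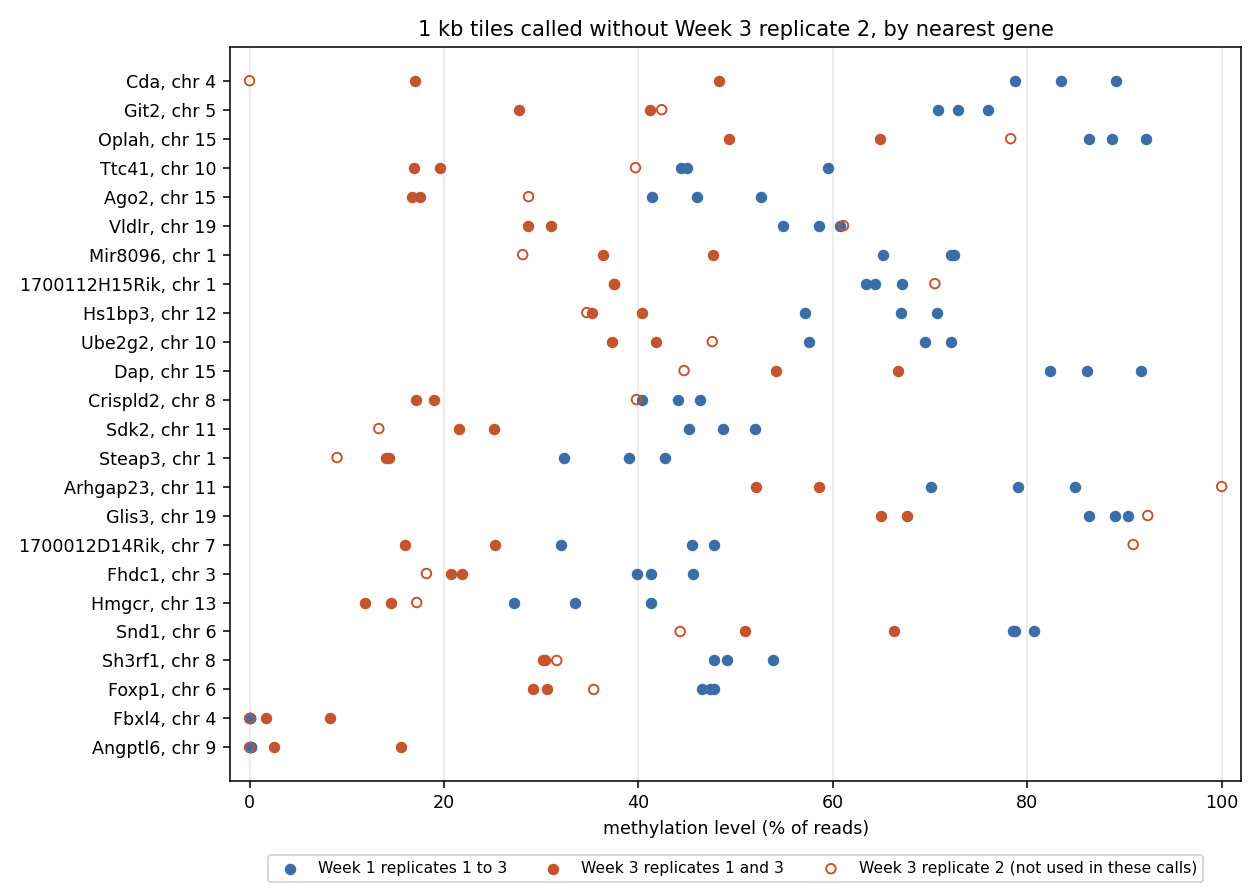
Methylation level (percent of reads) of the 24 tiles called without Week 3 replicate 2, each point a library and the open points the library left out of those calls. In 22 tiles Week 3 replicates 1 and 3 lie below every Week 1 library.

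The comparison of promoter methylation with expression asked whether both changed at the same genes. Of the panel genes that rose, Col10a1, Mmp13, Runx2 and Col1a1 had no promoter tested here. The promoters of others stood low at both weeks: Ihh at 0.41% ± 0.38 and 0.99% ± 1.46, Mki67 at 0.43% ± 0.37 and 0.50% ± 0.74, and Acan at 0.07% ± 0.13 and 4.03% ± 6.37. The Week 3 level of Acan came from replicate 2, at 11.4% against 0 and 0.7%, and without it the difference was 0.29 points. The Alpl promoter stood at 10.0% ± 1.66 and 10.2% ± 1.32. The Spp1 promoter, with 3 sites, went from 56.2% ± 8.87 to 33.2% ± 4.95 (p = 0.0018, adjusted p = 0.656 by the quasi-binomial test). The smallest promoter p values belonged to Hpgd, a prostaglandin dehydrogenase (0.14% ± 0.24 and 8.14% ± 2.54), Syt8 (21.5% ± 2.01 and 10.0% ± 2.57) and the unnamed clone 5730522E02Rik (2.24% ± 0.59 and 0.05% ± 0.08), each with an adjusted p of 0.656. Hpgd and Syt8 expression rose, by log2 changes of 3.29 and 1.11. Across 10621 genes the promoter difference and the log2 change had a Spearman's rho of -0.027 (permutation p = 0.00571) and a Pearson's r of -0.005 (permutation p = 0.574), and genes are not independent replicates. The rho was -0.019 without Week 1 replicate 1 (permutation p = 0.0568), -0.018 at coverage of at least 20 reads (0.191) and -0.014 with 1000 bases on either side of the 5' end (0.13), and did not pass in these 3 settings. Because 0 promoters were called, the overlap of called promoters and called genes was 0.

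At Week 1, promoters of genes below the count filter had a median level of 2.80%, with 19.8% of them above 50%, against a median of 0.50% and 0.8% above 50% for genes at 50 CPM or more. Among promoters at an unadjusted p under 0.05, those that gained methylation held 54 genes whose expression rose against 74.6 expected (odds ratio 0.67, Fisher's exact p = 0.00589, adjusted p = 0.0236 over the 4 direction pairs). The pair of lower methylation and higher expression held 87 genes against 76.9 expected (Fisher's exact p = 0.197). In the 5 libraries other than Week 3 replicate 2, the first pair held 63 against 76.9 (Fisher's exact p = 0.0812, adjusted p = 0.325).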

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

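The tests chosen only after the result had been seen were those of shallow depth, of few template molecules, of noise in the calling libraries and of reads counted as independent draws, as were the fits that left out Week 3 replicate 2 by joining sites over 5 libraries.

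In the ERRBS library of Week 3 replicate 2, 21.1% of sites at 40 to 60% in the other libraries stood at exactly 0 or 100%, against 0.01 to 1.86% in the other 5 libraries. Shallow depth is argued against, because Week 1 replicate 1 thinned to the same coverage had 0.23% of such sites against 22.1% in Week 3 replicate 2. Uniform methylation within that culture, a biological explanation, is also argued against, because in 35.3% of the CpGs with both strands at an end (55 of 156) the strands stood at opposite ends. Few template molecules may account for the pattern: the strands differed as if each held 3.19 effective molecules, against 8.17 to 31.1 in the other libraries. Loss of DNA before amplification is a technical explanation of so few molecules, and it was not tested on its own.

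Without Week 3 replicate 2, 22 of the 24 tiles called were lower at Week 3, and in the 5 libraries joined alone 33 of 35 were, against at most 9 tiles called in any of the other 9 splits of those libraries. A genome-wide loss of methylated calls in bisulfite treatment is argued against, because other tiles of like level changed by a median of -0.28 points against -25.9 points in the tiles called. Noise in the libraries that made the calls stays open: in the library left out, 14 of the 22 tiles lay nearer the other Week 3 libraries (one-sided exact binomial p = 0.143), and its median change from the Week 1 mean was -18.3 points against 0.61 in other tiles. A first form of that test, against the Week 1 mean alone, gave 17 of 22 tiles below it against 48% of other tiles (one-sided exact binomial p = 0.00503), and it was replaced after it had been seen, because selecting tiles on the Week 1 level inflates that count and that median. Longer culture remains a candidate explanation that these 6 libraries could not separate from noise.

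The logistic test without an overdispersion term called 43447 sites between the weeks. It called as many or more in 3 of the 10 splits of the 6 libraries, the real one included, with 54583 in the highest of the others. Reads counted as independent draws may therefore account for those calls, since sets of libraries that mix both weeks gave as many. No biological explanation of these calls was tested.

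For the tests that allow for spread between replicates, 10 splits are too few to give a share under 0.05. The real split called 5361 genes and the highest other 0. For gene lists, by camera at the preset correlation, the real split called 14. Each other split, mixing both weeks, called 4 to 11 lists with 0 genes called. List calls by this test therefore also arose where no gene passed. For sites, tiles and promoters the real split and the highest other both called 0 by the quasi-binomial test. In the real split 38717, 4603 and 988 had an unadjusted p under 0.05, and edgeR called 7 sites.

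Mitochondrial CpG sites, which no comparison used, showed methylated reads above the level that a count of 0 would allow (0.00127 to 0.00491%): 0.2%, 0.386% and 0.445% in Week 1 replicates 1, 2 and 3, and 0.207%, 0.408% and 0.344% in Week 3 replicates 1, 2 and 3. That level covers counting error only, so these reads cannot be told apart from incomplete bisulfite conversion or sequencing error.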

How the results depend on the processing

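The tests chosen after the data had been seen were the sum over transcripts, replicates 1 and 3 alone, the ERRBS sites joined over 5 or 4 libraries, limma weights and promoters at the counted transcript. The genes called ranged from 3980 to 5762 with 1 library left out and from 4464 (DESeq2) to 6306 (replicate block) otherwise, apart from 742 with glmTreat at 1.5-fold, a stricter hypothesis. Gene lists called ranged from 13 to 16 with 1 library left out, and were 18 with fry, 15 with the replicate block and 1 with an estimated correlation, whose preset was 0.01. In RNA-seq the replicate block kept 5347 of the 5361 genes called, and among the lists and the genes set by the naming rule it changed no call other than those given beside their results and that of Hoxa10 (adjusted p = 0.0504 without the block and 0.0362 with it). The ERRBS libraries share only a number (correlations of same-numbered libraries 0.008, 0.011 and 0.004), and with the replicate block 0 sites, 0 tiles and 0 promoters were called and the mean difference was -0.305 points (exact sign-flip p = 0.25). Sites called were 43447 without overdispersion, 5343 when an adjusted p under 0.01 and 25 points were also asked, 7 with edgeR, 7 over the 5 libraries joined, and 0 to 6 with 1 library left out. Tiles called were 15808 without overdispersion, 35 over 5 and 42 over 4 libraries joined, and 0 to 24 with 1 library left out. Promoters called were 4564 without overdispersion and 0 with each other setting. The mean methylation difference was 5.775 points when reads were pooled, which weights sites by depth, and -0.394 to -0.222 with 1 library left out. Spearman's rho of promoter methylation and expression was -0.018 at coverage of at least 20, -0.014 with 1000 bases on either side, and -0.032 to -0.019 with 1 library left out. Apart from the stricter hypothesis of glmTreat and the independent reads of the test without overdispersion, the cause of these shifts was not tested.

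Results that turned direction were uncalled in each case, and the cause was not tested. The posterior and limb Hox genes list did so without Week 1 replicate 2 (adjusted p = 0.986), Week 3 replicate 1 (0.874) or Week 3 replicate 2 (0.961) and with replicates 1 and 3 alone (0.883). Col2a1 gave -0.205 without Week 1 replicate 2 and -0.167 with replicates 1 and 3 alone, where Vwf gave 0.027. Nfatc1 gave 0.139 without Week 1 replicate 1, 0.020 without Week 1 replicate 3, 0.005 without Week 3 replicate 2 and 0.030 with transcripts summed. Among promoters, in points, coverage of at least 20 turned Alpl (-1.10), Sox9 (0.36), Dnmt3a (-0.29) and Dnmt3b (-0.63), and 1000 bases on either side turned Alpl (-1.93), Col2a1 (-1.02) and Dnmt3b (-0.60). Sites joined over 5 libraries turned Alpl (-0.27), Dnmt3b (-0.17) and Tet2 (0.71), and over 4 libraries Col2a1 (-0.16), Mki67 (-0.43), Dnmt3b (-0.80), Tet2 (0.48) and Tet3 (-0.10). Leaving out Week 1 replicate 1 turned Alpl (-0.34) and Sox9 (0.05), Week 1 replicate 2 Alpl (-0.32), Week 1 replicate 3 Col2a1 (-0.18) and Mki67 (-0.15), Week 3 replicate 2 Sox9 (0.10), and Week 3 replicate 3 Ihh (-0.26), Alpl (-0.53), Mki67 (-0.36) and Dnmt3a (-0.07). At the other end of the range with 1 library left out, the Hox list had an adjusted p of 0.799 (without Week 3 replicate 3), Col2a1 a log2 change of 0.321 (without Week 1 replicate 1) and Nfatc1 one of -0.209 (without Week 1 replicate 2). In promoters, that end was 1.08 for Ihh, 0.32 for Mki67 and 0.30 for Dnmt3a without Week 3 replicate 2, 1.11 for Alpl without Week 1 replicate 3, and 2.03 for Col2a1 without Week 1 replicate 2. Over all alternatives, 1837 of 1964 values for single genes, 237 of 275 for lists, 156 of 186 for promoters and 106 of 142 for tiles kept direction and side of the threshold, and 53 of the 105 genes' values that lost a call did so under glmTreat. In tiles of intermediate level the 6-library methylation test had little power, since it recovered the simulated 20-point changes in 0 of 100 tiles. Power at low or high levels, and for single sites and promoters, was not simulated.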

Other observations

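The tests in this part were written before their results were seen, but example genes outside the rule for named genes, and the 5-library join that gave the tiles of the first hypothesis, were chosen afterwards. In the inflammation and NF-kB list, 8 of 18 members fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.000424, and adjusted p = 0.295 with an estimated correlation). The complement factor Cfb fell by 1.29 on the log2 scale, from 43.4 ± 5.73 to 17.8 ± 2.82 CPM, the nitric oxide synthase Nos2 by 1.56 and the cytokine Lif by 1.22. In the macrophage and leukocyte list 6 of 13 members fell and 0 rose, but 1 fell without Week 1 replicate 1 and 3 without Week 3 replicate 2 (camera adjusted p = 0.0715, adjusted p = 0.684 with an estimated correlation, and 0.00466 with the replicate block). The chemokine Cxcl12 was the inflammation member that rose, by a log2 change of 0.83. In the interferon response list, 5 of 19 rose and 2 fell, the same adjusted over the list alone, and camera did not pass (adjusted p = 0.189; fry adjusted p = 0.0181). The falls came to 1 without Week 1 replicate 1, 2 or 3 or Week 3 replicate 1 or 3. Ifit2 rose 1.71-fold, from 11.3 ± 0.416 to 19.3 ± 1.01 CPM.

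In the hypoxia and glycolysis list, 9 of 20 fell and 3 rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.0297, and adjusted p = 0.544 with an estimated correlation). Hk2, which phosphorylates glucose, fell by 0.49 on the log2 scale, from 390 ± 3.38 to 278 ± 12.5 CPM, Eno1 by 0.44 and Ndrg1 by 0.42. The list's call was lost without Week 1 replicate 2 (adjusted p = 0.0871) or Week 3 replicate 2 (adjusted p = 0.056). Its rises came to 0 without Week 1 replicate 1 or 3 or Week 3 replicate 3, 1 without Week 3 replicate 1 and 5 without Week 1 replicate 2. In the oxidative phosphorylation list, 6 of 26 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.413), with Ndufa4 lower by a log2 change of -0.38 and Cox7b higher by 0.32. Without Week 1 replicate 2, 8 fell and 5 rose, and without Week 1 replicate 1 or 3 or Week 3 replicate 1 or 3, 1 rose. In the ER stress and unfolded protein response list, 6 of 20 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.396). Its falls came to 2 without Week 1 replicate 1 or 3 or Week 3 replicate 1. Atf5 and Chac1 rose 1.98-fold and 1.76-fold, and Ddit3 fell by 0.68 on the log2 scale. In the cholesterol synthesis list, 7 of 20 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.116; fry adjusted p = 0.0475), with Mvk 1.70-fold and Hmgcs1 1.36-fold higher, and 2 fell without Week 1 replicate 2 and 1 without Week 3 replicate 3. In the posterior and limb Hox genes list, 2 of 16 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.96), with a median log2 change of -0.02 and a mean of 0.05. No member fell without Week 1 replicate 1 or 3 or Week 3 replicate 2 or 3, and without Week 1 replicate 1, 1 rose.

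A first hypothesis was that genes overlapping the tiles with lower methylation had changed in expression. Of the 24 tested genes that overlap a tile called lower in the 5 libraries joined alone, 10 had changed (41.7%), against 38.4% of other genes overlapping tested tiles (Fisher's exact p = 0.834), so the small number of tiles leaves this open. A further hypothesis was that methylation within gene bodies moved with expression. Across 7786 genes Spearman's rho was -0.014 (permutation p = 0.229) and Pearson's r was -0.022 (permutation p = 0.0536), and neither passed. The last was that promoters of genes that rose at least 4-fold had lost methylation where there was some to lose. Of their 88 tested promoters, 9 stood at 10% or more at Week 1, with a median change of 0.15 points against -0.40 in other such promoters (one-sided permutation p = 0.608), and 9 promoters are too few to settle it.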
